A study of Paxillus involutus ATCC 200175 with 12 samples.

How the data were processed

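Gene expression of the ectomycorrhizal fungus Paxillus involutus was measured on 12 subarrays of 1 single-colour NimbleGen slide, hybridised with Cy3-labelled double-stranded cDNA made from total RNA. Per the labels, mycelium was grown axenically on glass beads for 9 days, starved of nitrogen for 24 h and then kept for 7 days with a hot-water extract of maize compost from which particles over 0.2 um and compounds under 10 kDa had been removed. The extract was given alone (OM), with glucose (OM+G), with ammonium (OM+N) or with both (OM+N+G), and each group held 3 arrays. The series' design text speaks of 3 separate cultures, read here as 3 per group, so the p-values measure the spread between cultures together with that between subarrays of 1 slide. The amounts of glucose and ammonium are not given in the sources used here.

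The deposited values are RMA values, 1 per feature and array, made by the authors per the submitters' processing notes. The software and its version are not given in the sources used here. The deposited values were read as log2 from their range and from the scale RMA usually returns. By the probe counts in the files, 12203 of the 12214 features were summarised from 10 probes and 11 from fewer, and 1 further feature was a random-sequence control summarised from 10000 probes. The control was left out of all tests. The deposited table of the series and the 12 per-array files held identical log2 values for every feature. Each array file also has a column of scores named by the authors as an error of the expression value, but the deposited scores lie between 0 and 1 and rise with the expression value. Their meaning is not stated, and they were not used. The other deposited column, a count of probes per feature, served only for the statements above.

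In its usual form RMA corrects the background, makes the probe distributions of the arrays equal and summarises over probes, so a change of total mRNA cannot be seen, and each change is relative to the other features of the array. The background correction and the summary could not be varied, because only summarised values were used here. The number of arrays limits the precision, and no detection call comes with the values. The features carry running numbers (paxillus_1 and so on). The files do not pair them with gene names, and 0 of the 12214 feature IDs matched an entry of the reference gene table of the genome assembly of this fungus, which holds 18033 genes. No gene function is therefore given, and the gene lists fixed in advance could not be tested.

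A mean per group was fitted to all 12 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), which left 8 residual degrees of freedom plus 4.72 from the prior. Contrasts were OM+G minus OM, OM+N+G minus OM+N, OM+N minus OM, OM+N+G minus OM+G, OM+N+G minus OM, the averages of both glucose and of both ammonium contrasts, and the interaction, defined as the glucose change with ammonium minus the glucose change without it. A feature was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast over all 12214 features, with no fold-change minimum and no filter on dim features. All adjusted p-values in the text come from limma unless another tool is named. Errors of log2 fold changes are limma's moderated standard errors (SE), and errors of levels are standard deviations (SD, n = 3).

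The contrasts, their tests and the alternatives were fixed before the data were examined, except those named as chosen later. The scores on the glucose axis, the classes of features and the check of same-numbered arrays were not part of that plan. Nor were the counts by feature number and their permutations. The rule for naming features was the pair with the largest rise and the pair with the largest fall in each contrast, among called features whose arrays did not overlap between the groups compared. For averaged contrasts both underlying comparisons had to be free of overlap, and for the interaction no such condition could be set. On simulated data with the residual spread of the 12214 real features and 200 changed features, the contrast of OM+G minus OM recovered 26% of changes of 0.25 on the log2 scale, 84% of changes of 0.5 and 100% of changes of 1. For the interaction the shares were 8%, 54% and 94%, and the simulations gave 10 and 6 false calls. Far more features were called for glucose in the real data, and the simulated noise was independent between features. The shares and false calls need not carry over to the real contrasts.

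The alternatives were the values of the series table, cyclic loess between arrays, scaling to the 75th percentile, leaving out the dimmest 25% of features, an intensity trend with robust moderation, array weights (gene-by-gene method, since the default did not converge), fits to the arrays of one contrast alone, the replicate number as a block, a log2 fold minimum of 1, and leaving out each array in turn. A quantile normalization of the summarised values, leaving out features with a mean under 6, and leaving out both OM replicate 2 and OM+N replicate 1 were added after the data were seen, as was the comparison of directions between bright and dim features.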

Results

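Transcript levels of 12214 features were measured in mycelium of Paxillus involutus, a fungus that lives in symbiosis with tree roots, in 4 groups of 3 cultures. The groups form a 2 by 2 design of glucose and ammonium added to an extract of organic matter, and the question was how carbon and nitrogen supply govern the fungus's use of litter. Array medians lay between 11.74 and 11.78 on the log2 scale. The random-sequence control lay between 3.66 and 3.80, and 715 features with a mean under 6 over all arrays lay close to it (median 3.63). The remaining 11499 features had a median of 11.83. Within groups, arrays correlated with r between 0.993 and 0.999 across features, and arrays with and without glucose with r between 0.954 and 0.988. These correlations include the 715 features near the control level, whose distance from the rest raises r. The first principal component held 80.1% of the variance and separated the arrays with glucose from those without. Arrays without glucose occupied subarrays 1 to 6 and those with glucose subarrays 7 to 12, so the position on the slide and glucose cannot be told apart. Each group held its own run of consecutive subarrays, so the ammonium changes and the interaction cannot be told apart from position either.

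The first comparison asks how glucose changed the transcriptome on organic matter alone. In the absence of ammonium, 8088 of 12214 features changed between OM and OM+G, 3643 upward and 4445 downward. Most changes were small: the median rise was 1.35-fold and the median fall 1.33-fold, and 133 called features changed at least by 1 on the log2 scale, 131 of them upward. paxillus_316 rose from 10.29 ± 0.97 in OM to 12.66 ± 0.09 in OM+G (log2, SD, n = 3), a log2 change of 2.37 (SE 0.33, limma adjusted p = 5.75e-05). paxillus_10 rose from 11.47 ± 1.24 to 13.79 ± 0.07, by 2.32 (SE 0.41, limma adjusted p = 0.000326). The strongest falls were those of paxillus_6517, with a log2 change of -1.06 (SE 0.06, limma adjusted p = 1.86e-06), and paxillus_4689, with -1.05 (SE 0.11, limma adjusted p = 9.4e-06). Arrays of both groups did not overlap for 8755 features (71.7%), against 10% expected by chance for 3 against 3. OM replicate 2 lay apart from the other OM arrays: without it paxillus_10 changed by 3.03 and paxillus_316 by 2.92, which turns their order, and 8364 features were called.

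With ammonium present, glucose changed 8963 features, 3990 upward and 4973 downward. The median rise was 1.43-fold and the median fall 1.39-fold, and 623 called features changed by at least 1 on the log2 scale, 480 upward and 143 downward. paxillus_10 rose from 10.76 ± 0.25 in OM+N to 13.89 ± 0.07 in OM+N+G (log2, SD, n = 3), an 8.76-fold difference (log2 3.13, SE 0.41, limma adjusted p = 1.92e-05), and paxillus_316 rose 7.07-fold (log2 2.82, SE 0.33, limma adjusted p = 7.99e-06). paxillus_12663 fell by 1.32 on the log2 scale (SE 0.10, limma adjusted p = 6.66e-07) and paxillus_12498 by 1.28 (SE 0.09, limma adjusted p = 5.09e-07). Arrays did not overlap for 9275 features (75.9%, against 10% by chance). OM replicate 2 lay towards the glucose arrays and OM+N replicate 1 away from them, which adds to the difference between both glucose contrasts. Without these arrays 8563 features were called without ammonium and 8701 with it. The counts of changes by at least 1 were not recomputed without them.

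The glucose responses at both ammonium levels, which share no arrays, went the same way in most features. The log2 changes correlated with Pearson's r of 0.94 and Spearman's rho of 0.94 across features, which are not independent replicates. Both contrasts called 7475 features in the same direction: 3298 rose in both and 4177 fell in both, against 1190 and 1810 expected of independent lists. A further 42 features were called in opposite directions, and 32 of these passed the interaction test. The expected values are only a guide, because both lists share each feature's estimate of spread. Averaged over ammonium, glucose changed 9534 features, 4321 upward and 5213 downward. The excess of falls depended on the processing, with 4663 upward and 4650 downward after cyclic loess, 3795 and 5785 after scaling to the 75th percentile, and 3813 and 3799 without the dimmest 25% of features. For the single contrasts cyclic loess gave 3927 upward and 3932 downward without ammonium and 4345 and 4362 with it. paxillus_10 (log2 2.73, SE 0.29, limma adjusted p = 1.89e-06) and paxillus_316 (log2 2.60, SE 0.23, limma adjusted p = 4.52e-07) led the rises. paxillus_4689 (log2 -1.16, SE 0.08, limma adjusted p = 5.11e-08) and paxillus_12663 (log2 -1.15, SE 0.07, limma adjusted p = 4.29e-08) led the falls.

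The direction of the glucose response differed between bright and dim features in the RMA values. Among the brightest 25% of the features with a mean of at least 6 over all arrays, 1559 of 2875 (54.2%) rose and 882 (30.7%) fell with glucose on average. Among the dimmest 25%, 634 of 2875 (22.1%) rose and 1693 (58.9%) fell. After scaling to the 75th percentile, 49.4% of the brightest rose and 34.3% fell, against 18.5% and 64.1% of the dimmest, and after quantile normalization 43.9% and 37.5%, against 33.9% and 44.8%. After cyclic loess, which removes trends with intensity by construction, the shares were 43.0% and 38.3% of the brightest and 38.2% and 39.7% of the dimmest. The interquartile range of an array was wider with glucose, at 1.26 ± 0.01 (log2, SD, n = 3) in OM+G and 1.26 ± 0.003 in OM+N+G, than without it, at 1.09 ± 0.03 in OM and 1.07 ± 0.02 in OM+N. Of the 715 features near the control level, 78 were called for glucose on average.

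**Figure D1:**
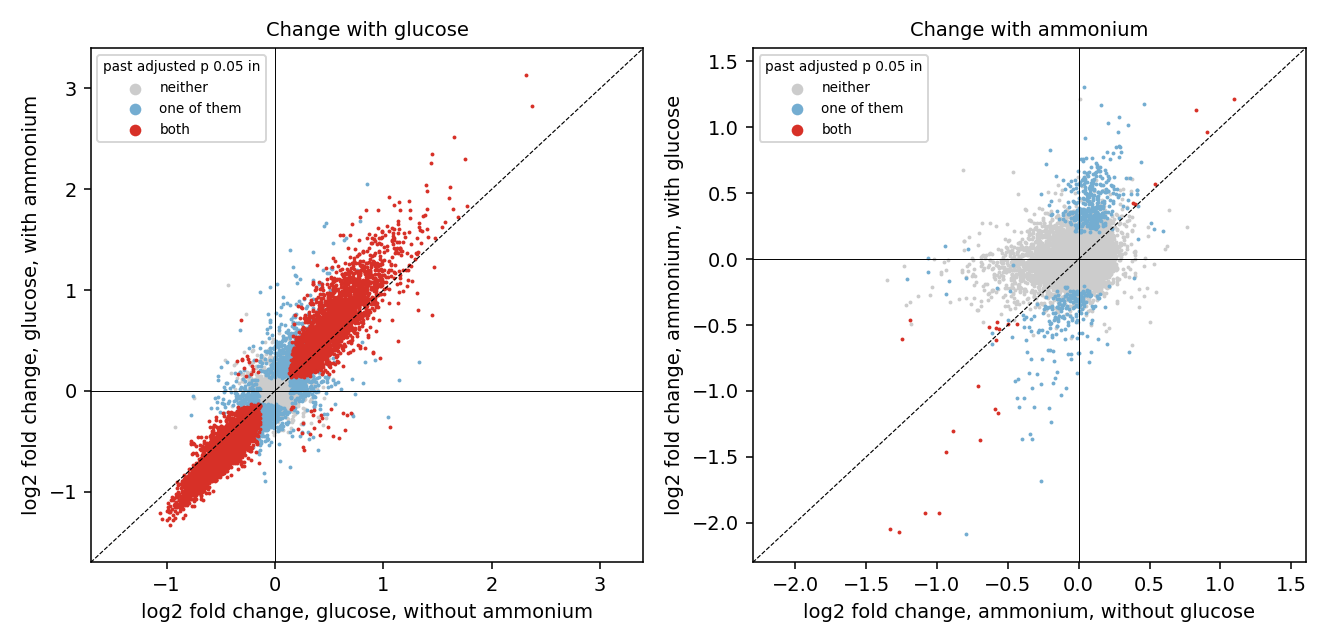
Log2 fold change of each feature with glucose (left, without ammonium on the x axis and with it on the y axis) and with ammonium (right, without glucose on the x axis and with it on the y axis), coloured by the number of contrasts in which limma's adjusted p is under 0.05; the dashed line marks equal change. The glucose changes correlate with r = 0.94, and their root mean square is 0.53 with ammonium and 0.42 without it. OM replicate 2 lies towards the glucose arrays and OM+N replicate 1 away from them, which adds to this difference. The root mean squares were not recomputed without these arrays. The ammonium changes scatter widely (r = 0.27).

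The next comparison asks how ammonium changed the transcriptome on organic matter alone. Between OM and OM+N, 41 features changed, 11 upward and 30 downward, and 1851 had an unadjusted p under 0.05. paxillus_11336 rose from 12.56 ± 0.21 to 13.65 ± 0.09 (log2, SD, n = 3), by 1.09 (SE 0.09, limma adjusted p = 0.000129), and paxillus_285 rose by 0.91 (SE 0.15, limma adjusted p = 0.0212). paxillus_6442 fell from 13.02 ± 0.23 to 11.69 ± 0.31, by 1.33 (SE 0.14, limma adjusted p = 0.000763), and paxillus_6443, the next feature in the numbering, by 1.27 (SE 0.15, limma adjusted p = 0.00236). Arrays did not overlap for 1941 features (15.9%, against 10% by chance). The count depended on the arrays used: it was 21 without OM replicate 1, 27 without OM+N replicate 3, 96 without OM+N replicate 2 and 132 without OM replicate 3. Without both OM replicate 2 and OM+N replicate 1 it was 53, with 29 upward and 24 downward. A fit to these 6 arrays alone called 3 features, with adjusted p of 0.219 for paxillus_285 (0.112 without OM replicate 1 and 0.0994 without OM+N replicate 3 in the fit of all groups), 0.052 for paxillus_6442 and 0.0703 for paxillus_6443 by limma.

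In the presence of glucose, ammonium changed 597 features, 362 upward and 235 downward, with a median rise of 1.32-fold and a median fall of 1.33-fold. paxillus_3701 rose from 11.51 ± 0.05 in OM+G to 12.81 ± 0.05 in OM+N+G (log2, SD, n = 3), by 1.30 (SE 0.08, limma adjusted p = 3.52e-06), and paxillus_11336 rose by 1.21 (SE 0.09, limma adjusted p = 9.47e-06). paxillus_9370 fell from 12.88 ± 0.22 to 10.80 ± 0.11, a log2 change of -2.09 (SE 0.16, limma adjusted p = 1e-05), and paxillus_6443 changed by -2.07 (SE 0.15, limma adjusted p = 9.47e-06). Of the 29 called features that changed by at least 1 on the log2 scale, 21 fell. Arrays did not overlap for 3310 features (27.1%, against 10% by chance). The count was 326 without OM+G replicate 1, 352 without OM+G replicate 2 and 358 without OM+N+G replicate 3.

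The ammonium contrasts without and with glucose, which share no arrays, called 25 features in common, 6 that rose and 19 that fell, against 0.326 and 0.577 expected of independent lists, and none in opposite directions. Both lists share each feature's estimate of spread, so they would not be independent even without an effect. Over all features the log2 changes of both contrasts correlated with Pearson's r of 0.27 and Spearman's rho of 0.19. Of the 597 features called with glucose, 481 had the same sign without it. Averaged over glucose, ammonium changed 585 features, 332 upward and 253 downward, and after cyclic loess 310 upward and 324 downward. paxillus_11336 (log2 1.15, SE 0.06, limma adjusted p = 1.86e-06) and paxillus_1285 (log2 0.98, SE 0.07, limma adjusted p = 6.8e-06) rose, and paxillus_6442 (log2 -1.69, SE 0.10, limma adjusted p = 1.86e-06) and paxillus_6443 fell (log2 -1.67, SE 0.11, limma adjusted p = 4.08e-06). The count was 389 without OM replicate 1, 329 without OM+G replicate 1, 387 without OM+G replicate 2 and 388 without OM+N+G replicate 3.

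Features that responded to both nutrients on average fell into unequal classes. The averaged glucose and ammonium contrasts are orthogonal in this design, although they rest on the same arrays and share each feature's estimate of spread. 186 features rose with both, against 117 expected of independent lists, and 172 rose with glucose and fell with ammonium, against 89.5 expected. Only 36 fell with both, against 108 expected, and 77 fell with glucose and rose with ammonium, against 142 expected. Over all features the log2 changes correlated with Pearson's r of -0.27 and Spearman's rho of -0.30, and 3164 of the 9534 features called for glucose had the same sign for ammonium. The OM arrays themselves lay apart from the mean of OM+N along the glucose response in the presence of ammonium, on a scale from 0 (OM+N) to 1 (OM+N+G): OM replicate 2 scored 0.39 and the other OM arrays 0.12 and 0.04. OM+N replicate 1 scored -0.37 on the matching scale from 0 (OM) to 1 (OM+G). OM replicate 2 and OM+N replicate 1 enter both averaged contrasts. Their deviations put part of the glucose response, with its sign turned, into the averaged ammonium change. The classes and correlations were not recomputed without these arrays, so their share in the pattern is not known. paxillus_285 belonged to the first class and stood at 11.07 ± 0.12 in OM, 12.40 ± 0.13 in OM+G, 11.98 ± 0.40 in OM+N and 13.36 ± 0.07 in OM+N+G (log2, SD, n = 3).

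Whether the response to one nutrient depended on the other was tested with the interaction. It was called for 90 features, 46 with a more positive ammonium change in the presence of glucose and 44 with a more negative one, and 1535 had an unadjusted p under 0.05. All 46 in the first class rose with glucose in the presence of ammonium, and 40 of them also rose with ammonium in the presence of glucose. paxillus_3701 was one of these: it lay at 11.37 ± 0.12 in OM, 11.51 ± 0.05 in OM+G and 11.41 ± 0.14 in OM+N, but at 12.81 ± 0.05 in OM+N+G (log2, SD, n = 3; interaction 1.26, SE 0.11, limma adjusted p = 0.000638). paxillus_887 instead was lowest with ammonium alone, at 12.48 ± 0.27 against 13.54 ± 0.18 in OM, 13.50 ± 0.02 in OM+G and 13.51 ± 0.09 in OM+N+G (interaction 1.07, SE 0.17, limma adjusted p = 0.0123).

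In the second class, 36 of the 44 features had their highest mean in OM+G, and 30 both rose with glucose in the absence of ammonium and fell with ammonium in the presence of glucose. paxillus_11908 lay at 12.32 ± 0.21 in OM+G, against 11.27 ± 0.29 in OM, 11.00 ± 0.03 in OM+N and 10.64 ± 0.13 in OM+N+G (log2, SD, n = 3; interaction -1.42, SE 0.19, limma adjusted p = 0.00648). paxillus_9370 lay at 12.88 ± 0.22 in OM+G and between 10.80 and 11.84 in the other groups (interaction -1.30, SE 0.23, limma adjusted p = 0.0238). The interaction count fell to 37 without OM replicate 1, 28 without OM+G replicate 1, 25 without OM+G replicate 2, 38 without OM+N replicate 3, 53 without OM+N+G replicate 1 and 48 without OM+N+G replicate 3. Without both OM replicate 2 and OM+N replicate 1 it was 129, with 49 in the first class and 80 in the second. Without OM+G replicate 2 the adjusted p of paxillus_9370 was 0.0802 by limma, it was over 0.05 in 6 of the 12 such refits, and it was 0.095 after quantile normalization.

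**Figure D2:**
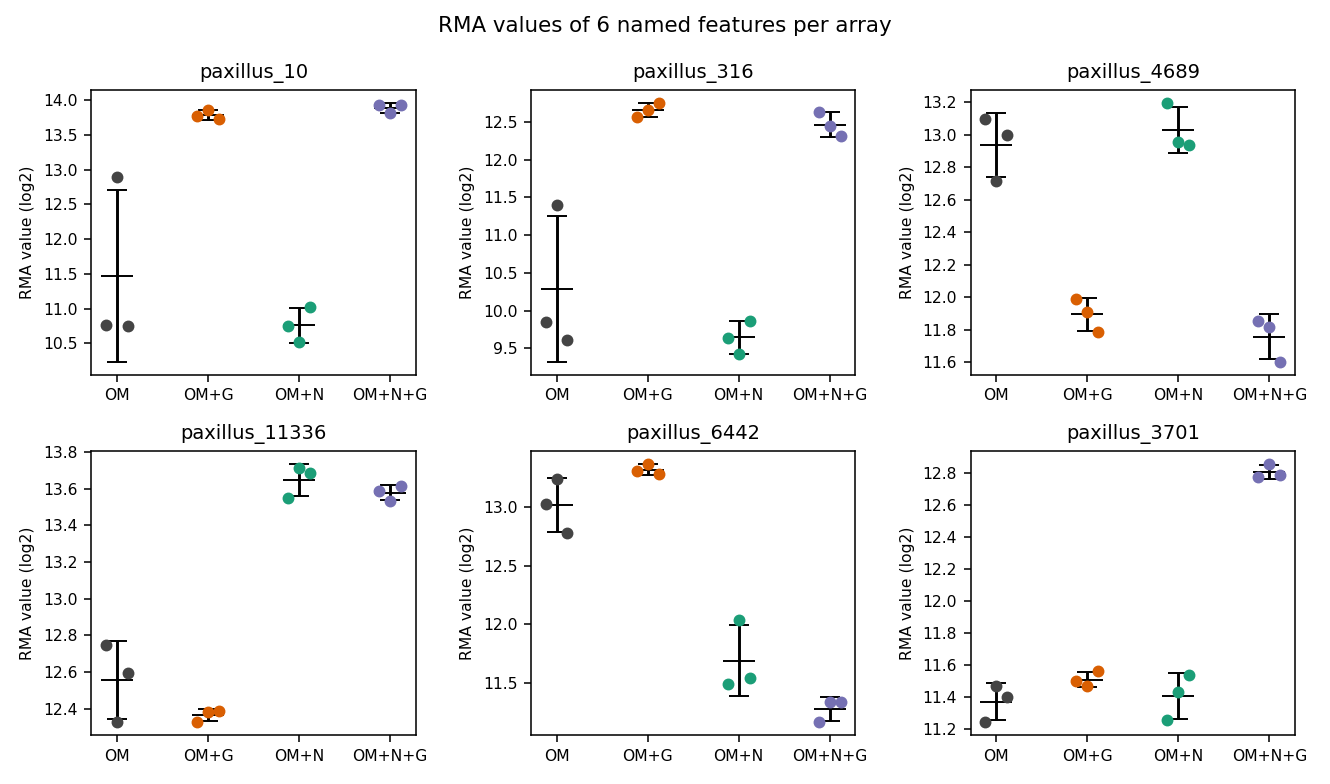
RMA values (log2) of 6 named features in each array (points), with the mean and SD of 3 arrays per group (bars), for OM, OM+G, OM+N and OM+N+G; each panel has its own y range. paxillus_10 and paxillus_316 are high with glucose, paxillus_4689 low with glucose, paxillus_11336 high with ammonium, paxillus_6442 low with ammonium, and paxillus_3701 high only in OM+N+G.

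Glucose and ammonium together changed 8183 features relative to OM, 3750 upward and 4433 downward, and 275 of them by at least 1 on the log2 scale. paxillus_10 rose by 2.42 (SE 0.41, limma adjusted p = 0.000211), or by 3.14 without OM replicate 2, and paxillus_285 rose by 2.29 (SE 0.15, limma adjusted p = 7.32e-07). paxillus_6442 (log2 -1.74, SE 0.14, limma adjusted p = 1.25e-06) and paxillus_6443 fell (log2 -1.72, SE 0.15, limma adjusted p = 2.22e-06). Arrays did not overlap for 8502 features (69.6%, against 10% by chance).

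The position of each array along the glucose response was scored on the axis between both groups of the other ammonium level, which holds none of its own arrays. A score of 0 stands for the mean of the group without glucose and 1 for that with glucose. The OM and OM+N scores thus lie on separate axes, each with its 0 at the other group's mean, and their opposite signs are 1 offset seen from both sides. The OM+G arrays scored 0.93 ± 0.03 (SD, n = 3) and the OM+N+G arrays 1.00 ± 0.01. Arrays without glucose were more spread: OM scored 0.18 ± 0.18, with 0.39 for replicate 2, and OM+N -0.20 ± 0.15, with -0.37 for replicate 1. These arrays had the lowest array weights of the series, at 0.27 for OM replicate 2 and 0.43 for OM+N replicate 1.

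**Figure D3:**
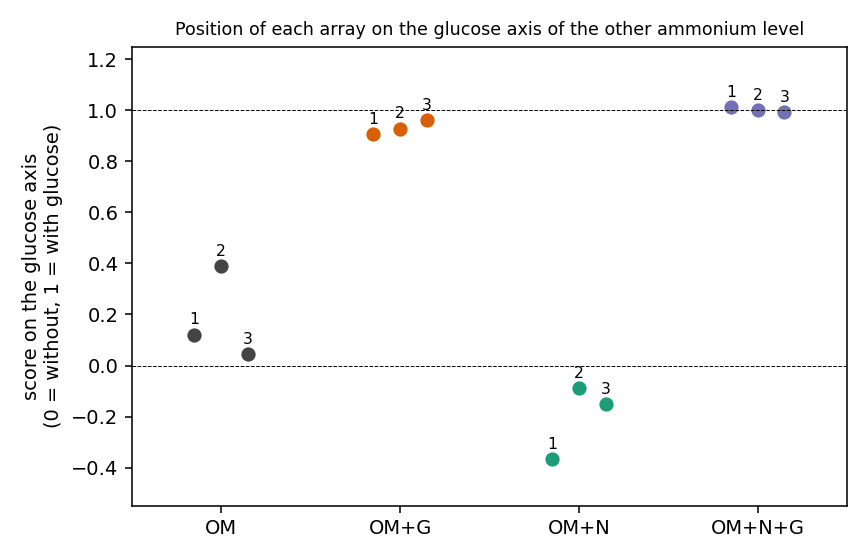
Score of each array on the glucose axis of the other ammonium level (y axis, no unit; 0 is the mean without and 1 the mean with glucose), by group, with replicate numbers above the points. Arrays with glucose lie between 0.91 and 1.01, and those without between -0.37 and 0.39.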

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

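The test of effect sizes and the splits with the ammonium effect removed were chosen after the results were seen; the other counts over splits of the arrays were fixed before. The test for a difference between the ammonium responses with and without glucose passed for 90 features. Among the named features it passed for paxillus_3701 (1.26), paxillus_887 (1.07), paxillus_11908 (-1.42) and paxillus_9370 (-1.30; all log2). Of 100 splits of the arrays within each glucose level, the real one included, 7 called at least as many interaction features, with 585 in the highest other split. This count says nothing on chance, because the splits carry the average effect of ammonium. The split with 585 calls exchanges the ammonium labels within 1 glucose level, which turns that effect into an interaction. Of the other 5, 4 shared 10 of 12 array labels with that exchange, and the one with 99 calls shared 8. With the averaged ammonium effect of each feature subtracted, 2 of the 100 splits called as many interaction features, the real one (90) included. The subtracted effect was estimated under the real labels, which leaves the real count as it was and can move only the others, down or up, so chance is not excluded. The other split called 241 and put OM replicates 1 and 2 with OM+N replicate 2, and OM+G replicates 1 and 2 with OM+N+G replicate 3, which may point to a structure among the arrays that was not tested.

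Ammonium called 597 features with glucose and 41 without it. The arrays without glucose were more spread (root mean square SD of 0.142 in OM and in OM+N, against 0.106 in OM+G and 0.122 in OM+N+G), but the fit pools 1 spread per feature, and the median SE was 0.0765 in both ammonium contrasts. Over the 585 features called for ammonium on average, the median change in the called direction was 0.17 without glucose and 0.39 with it, and the ratio of 0.45 ranged from 0.37 (without OM replicate 2) to 0.51 (without OM replicate 3) over 12 fits that each left out 1 array. A wider spread alone would leave this ratio near 1, so the tables argue against it as the whole cause. Over all features the root mean square ammonium change was 0.161 without and 0.169 with glucose. Beyond array noise it was 0.122 and 0.132, but this noise was 1 value pooled over all groups. Given the wider spread without glucose, too little was taken off there and too much with glucose. The 1851 and 1962 features with an unadjusted limma p under 0.05 rest on the same pooled spread. These values therefore cannot show whether both responses were equally large over all features. A stronger ammonium response with glucose in those 585 features is a candidate explanation, as a hypothesis only.

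For the averaged contrasts the splits argue against chance. Of 100 splits, only the real split called as many features, both for glucose (9534, highest other 7507) and for ammonium (585, highest other 261). The real split also follows the runs of subarrays, so these counts do not separate a nutrient from position. The contrasts of 3 against 3 arrays have 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each: 8088 for glucose without ammonium, 8963 for glucose with ammonium and 8183 for both nutrients together (highest other 0 in each), 41 for ammonium without glucose (highest other 0) and 597 for ammonium with glucose (highest other 2).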

How the results depend on the processing

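The quantile, background-feature and two-array alternatives were chosen after the data were seen. Of 159 refits of the counts, 124 stayed within 1.5 times. The counts for glucose without ammonium, with ammonium and on average, and for both nutrients together, did so in every refit except under the log2 fold minimum of 1. With that minimum, the counts were 133, 623 and 300 for glucose (without ammonium, with it, on average), 275 for both nutrients, 9, 29 and 9 for ammonium (without glucose, with it, on average) and 9 for the interaction, a fall that follows from its construction. The count for ammonium without glucose (41) became 81 without the dimmest 25% of features, 72 with an intensity trend and robust moderation, 146 with array weights, 3 from the arrays of the contrast alone and 76 without background features. Array weights also gave 1238 for ammonium with glucose, 1131 for ammonium on average and 329 for the interaction. The interaction count was 144 with trend and robust moderation and 59 after quantile normalization. Fewer features or arrays enter some of these fits, and otherwise the cause was not tested.

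Leaving out 1 array at a time gave 21 (OM replicate 1) to 132 (OM replicate 3) for ammonium without glucose, 326 (OM+G replicate 1) to 473 (OM+N+G replicate 1) for ammonium with glucose, 329 (OM+G replicate 1) to 817 (OM replicate 3) for ammonium on average, and 25 (OM+G replicate 2) to 103 (OM replicate 2) for the interaction. Scaling to the 75th percentile moved the median averaged glucose change of all features to -0.10. Of 633 refits of the named changes, 619 kept direction and call, 14 lost the call and 0 reversed. The same replicate numbers occur in every group, but same-numbered arrays deviated together (r over 0.1) in 4 of 18 pairs, and 3 of 12 arrays correlated best with their own number, so they do not pair the arrays. With the number as a replicate block the counts stayed within 1.5 times (8006 for glucose without ammonium, 47 for ammonium without glucose, 64 for the interaction). The alternatives of the gene lists were not run, since no feature has a name here. Whether the 715 features near the control level are weakly expressed transcripts was not tested, which limits what can be said of such transcripts.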

Other observations

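All tests of technical explanations in this part were chosen after the results were seen. The large share of features called for glucose was set against scaling and position. Under cyclic loess, 75th-percentile and quantile scaling the averaged glucose count was at least 9313, against 9534 as reported, so it did not hinge on these scalings of the summarised values. The normalization within RMA could not be varied and was not tested. The groups of the ammonium contrasts lie 3 subarrays apart and those of the glucose contrasts 6. A linear trend along the subarray numbers alone would thus give ammonium 0.5 of the change of glucose, the bound set for the test. The larger ratio of root mean square changes beyond array noise was 0.287 (0.132 for ammonium with glucose, 0.460 for glucose on average). With the noise left in, these changes were 0.169 and 0.466. The ratio argues against a linear trend alone. A trend that is steepest between subarrays 6 and 7 would give a lower ratio, so other smooth trends stay open. A difference between subarrays 1 to 6 and 7 to 12 cannot be told apart from glucose, since 0 groups have arrays in both sets. It stays open beside a response to glucose, which the design names and which was not tested apart from position.

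OM replicate 2 scored 0.39 on the glucose axis of the ammonium arrays, where 0 and 1 are the groups without and with glucose, which argues against a swapped label. An admixture of RNA or signal from a glucose-fed culture stays open as a candidate explanation. The mixing fraction fitted on the linear scale was 0.331 (95% bootstrap interval 0.322 to 0.340) in 2048 rising features and 0.349 (0.343 to 0.354) in 2310 falling features, a difference of -0.0178, under the bound of 0.05 set for the test although the intervals do not overlap. The intervals come from resampling the features of 1 array, which are not independent replicates, and leave out the error between arrays. The mixing model left a residual 3.36% below that of a proportional log2 change. The fractions of that proportional change were 0.409 in rising and 0.297 in falling features. No biological explanation was tested.

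Of the 715 features with a mean under 6, 648 are among the 1610 numbered over 12000 and 67 are numbered 1001 to 2000. Over 14 blocks of 1000 consecutive numbers, the share of features with a mean of at least 6 that rose with glucose on average ranged from 10.8% (12001 to 13000, where 78.6% fell) to 58.3% (7001 to 8000, where 23.2% fell), with blocks between such as 3001 to 4000 (36.8% rose, 42.4% fell). For 2 blocks picked after these shares were seen, those after cyclic loess were 59.9% rising and 20.7% falling (7001 to 8000) and 16.1% and 67.3% (11001 to 12000, 11.6% and 75.6% as reported). Both members were called for ammonium on average in 72 of 10563 pairs of consecutive numbers, against a median of 29 and a highest value of 49 in 1000 permutations within blocks of 100 numbers.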
